A study of Lotus japonicus with 10 samples.

How the data were processed

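Total RNA from mature Lotus japonicus MG20 leaves was labelled with Cy3 and hybridised to 10 one-colour Agilent arrays, 1 array per sample. Per the labels' protocols, leaves were detached, submerged in 10 mM GSH and shaken at 200 rpm and 28 °C for the elicitation time, and the 4 unelicited samples are given a time of 0 h. Groups were taken from the sample titles: 4 unelicited, 3 GSH 3 h and 3 GSH 6 h. The deposited values are spot intensities on a linear scale from Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. Per the file headers the processed signal is background-subtracted and spatially detrended, and it is not normalized between arrays. The value table deposited with the series holds the same processed signal for all 6252 features of every array, with column medians from 14.5 to 65.9. No test or normalization between arrays is given in the sources used here.

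Each array has 5716 probes that are not controls, for 3148 names, 2568 with 2 probes and 580 with 1. Names came from the files' systematic name column and are kept as written. They are the design's own gene family names and loci, and none of the 40429 genes in the reference table used here carries 1 of these names as its symbol (0 matches). Names ending in the same locus were taken as 1 target, which gave 3082 targets, with 66 loci under 2 names. Names without a locus stayed separate targets. Targets with near-equal values, such as CYP73ALT_ntc and C4H02_LjSGA_003295.2, may therefore not be independent members of a list. No genome positions are given beyond the clone or chromosome part of a name.

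The signal was taken as log2 of the processed signal minus the array's 75th percentile over non-control probes, which lay between a signal of 227.25 and 1022.5. Spots marked as outliers by the scanner software (4 to 64 per array) were left out, and no spot was saturated. Probes were tested if well above background on every array of at least 1 group, which kept 3310 probes, 1 of them without an estimate, and 1971 targets. The depth of an array is given as the number of probes well above background, and the number of arrays limits the precision. Group means were fitted over all 10 arrays in limma 3.58.1 (R 4.3.3) with lmFit and eBayes (prior degrees of freedom 3.05), two-sided, with Benjamini-Hochberg adjustment over tested probes at 0.05. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

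The comparisons, the tests, the rule for naming genes, 33 gene lists given as text patterns and most alternative settings were fixed before the data were examined. The array carries short family names in place of descriptions, so 27 of the 33 lists met no name, markers of other organs and leaf cell types among them, and 5 had the 3 tested members required. A further 42 lists were written from the name prefixes after the names had been read and before any group difference was computed, so the report calls only the first kind planned. Lists were tested on 1 probe per target, the one with the highest mean over all arrays, with camera (preset correlation 0.01) and adjustment over the 47 lists tested. With a correlation estimated per list, 0 lists passed in any comparison (7, 8 and 1 at an unadjusted p under 0.05 at 3 h, at 6 h and between the times), while fry, which asks only whether a list's genes move one way on balance, called 42, 42 and 5.

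Named genes are, per comparison with unelicited leaves, the 12 largest rises and 8 largest falls, and between the times the 5 largest of each, among named probes that passed, were well above background on every array of the higher group and did not overlap between groups, with at most 2 of 1 description. To these were added up to 2 rises and 2 falls per list, or its brightest member where none passed, and any member of the phenylpropanoid and isoflavonoid lists. The text names a part of them. Where 2 probes of a name were tested (1303 names), their fold changes correlated at 0.966, 0.969 and 0.832 across names in the 3 comparisons, and both passed with opposite signs for 8, 2 and 0 names.

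Slide and scan coincide and were read from the file headers. They were used as a block, and the 8 arrays of slide 2 were fitted alone. The concordance of the 3 h and 6 h changes was set beside 100 simulated draws of unchanged groups sharing the unelicited arrays and 6 values with those arrays divided between the comparisons. The code was tested on simulated data with 200 changed probes of 3309: at log2 changes of 1, 2 and 4 the fit recovered 8.45%, 56.4% and 96.1% at 3 h with 6 false calls and 11.3%, 59.0% and 96.1% at 6 h with 7, and the list test called the 1 list that had been raised. Alternatives covered background correction, scaling, the filter on dim probes, the variance model, blocks, 1 probe per target and each array left out. The mean spot signal is not a column of these files, so normexp (offset 50) was run on the median spot and background signals.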

Results

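Gene expression was measured in mature leaves of Lotus japonicus MG20, a model legume, before and after elicitation with 10 mM glutathione (GSH), a tripeptide thiol used here as an elicitor of defence responses. Cy3-labelled RNA was hybridised to 10 one-colour Agilent arrays, 4 from unelicited leaves, 3 from leaves kept in GSH for 3 h and 3 from leaves kept in GSH for 6 h. The array is a focused design with 5716 probes for 3148 gene names, chiefly transcription factors, cytochrome P450s, glycosyltransferases, beta-glucosidases and genes of phenylpropanoid and isoflavonoid metabolism. Between 2644 and 3805 probes per array (46.3% to 66.6%) were well above background, and no spot was saturated. The small number of arrays limits the precision of every value below.

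All values are log2 signals minus the array's 75th percentile, and the comparisons cover 3309 probes. The labels describe the arrays of a group as biological replicates and say no more about how plants or leaves were shared, so a p-value here measures the spread between these samples. Unelicited replicates 1 and 2 were on slide 1 with scan 1, and the other 8 arrays were on slide 2 with scan 2. Across probes, unelicited arrays correlated at 0.973 to 0.978 within a slide and at 0.827 to 0.853 between slides, while unelicited and GSH arrays correlated at 0.325 to 0.452, or 0.368 to 0.452 within slide 2. Where a probe was not well above background on any array of a group, its fold is given as "at least N-fold", the brighter group's mean against the higher of the dim probe's own signal and the lowest well-measured signal on each array.

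The first comparison asks which genes differ after 3 h of elicitation. Genes at the entry to phenylpropanoid metabolism and in chalcone synthesis were mostly higher. Probes for cinnamate 4-hydroxylase, the second enzyme of the phenylpropanoid pathway, rose, with unelicited signals that differed by probe and slide. On 1 probe each, not well above background in unelicited leaves, CYP73ALT_ntc went from a log2 signal of −7.00 ± 1.06 (SD, n = 4) to 6.32 ± 0.22 (n = 3), at least 2764-fold higher, and C4H02_LjSGA_003295.2 from −6.97 ± 1.02 to 6.08 ± 0.21, at least 2342-fold higher. Their other probes rose by 8.76 (SE 1.34) and 8.69 (SE 1.28) from unelicited signals of 0.99 and 0.91 on slide 1 and −4.40 and −4.23 on slide 2, so the size of these rises depends on the probe and the slide. Among 35 tested targets of phenylpropanoid entry (phenylalanine ammonia-lyase, cinnamate 4-hydroxylase and coumarate ligase names), 26 rose, 6 fell and 3 did not pass, with a median log2 fold change of 4.22 (camera adjusted p = 0.00125; adjusted p = 0.341 with an estimated correlation). A phenylalanine ammonia-lyase probe, PAL09_chr5.LjT17D03.50.nd, fell by 4.11 (SE 0.54, adjusted p = 5.70e-05).

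Of 41 tested targets of chalcone synthesis, 25 rose, 10 fell and 6 did not pass, with a median of 5.54 (camera adjusted p = 0.0107; adjusted p = 0.542 with an estimated correlation). CHR04_CM1092.70.nc and CHR05_CM1092.80.nc, carrying names read here as chalcone reductase, rose by 7.56 (SE 0.86, adjusted p = 2.05e-05) and 7.57 (SE 0.87, adjusted p = 2.31e-05), or by 6.25 and 6.29 on slide 2 alone. CHR01_LjT35G18.140.nd went the other way, from 3.60 ± 0.31 (SD, n = 4) to below detection on all 3 arrays, at least 302-fold lower. The chalcone synthase probe CHS11_chr1.CM0593.380.nc fell from 4.67 (n = 3) to −2.33 ± 0.47 (SD, n = 3, adjusted p = 3.23e-06). On slide 2 alone it fell by 5.85, measured against 1 unelicited array, since the other spot was left out as an outlier. Downstream, in the isoflavonoid branch, 22 of 33 targets rose, 8 fell and 3 did not pass (median 3.60, camera adjusted p = 0.0665, not past the threshold). The isoflavone synthase family probe CYP93C_chr4.CM0692.280.nc rose from −0.07 ± 2.05 (SD, n = 4) to 6.93 ± 0.79 (n = 3, adjusted p = 6.43e-05), PTR1_chr3.CM0216.40.nd by 8.65 (SE 1.10, adjusted p = 4.70e-05) and CYP81ELT_1_ntc by 5.67 (SE 0.44, adjusted p = 1.52e-06), while HID8_chr4.CM0079.280.nc was at least 23.2-fold lower. On slide 2 alone CYP93C_chr4.CM0692.280.nc rose by 5.28 and PTR1_chr3.CM0216.40.nd by 6.70. In the narrower list of isoflavonoid and phytoalexin synthesis, written before the data were examined and met only by CYP81E and CYP93C names and their loci, 6 of 7 targets rose and 1, I2H1_chr2.CM0250.70.nc, fell by 2.05 (SE 0.29), the same 6 and 1 adjusted over the list alone. With normexp I2H1_chr2.CM0250.70.nc differed by −0.99 and did not pass (adjusted p = 0.0760). The list did not pass (median 4.64, camera adjusted p = 0.0876). The isoflavonoid glycosyltransferase name IFLGT03_chr4.CM0739.130.nd rose from −3.94 ± 0.56 (SD, n = 4) to 7.52 ± 0.38 (n = 3), while its list of 24 targets split into 8 up, 9 down and 7 not passing (median −0.11, camera adjusted p = 0.855). Unelicited arrays of slide 2 were above those of slide 1 by a median of 1.24 in chalcone synthesis and 1.47 in the isoflavonoid branch, and the median difference was −0.62 in phenylpropanoid entry.

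Several transcription factor families also moved at 3 h. WRKY factors were mostly higher: 55 of 74 targets rose, 6 fell and 13 did not pass, with the same 55 and 6 adjusted over the list alone (median 2.77, camera adjusted p = 3.37e-05; adjusted p = 0.274 with an estimated correlation). LjWRKY39 rose from −3.93 ± 0.79 (SD, n = 4) to 5.76 ± 0.03 (n = 3), LjWRKY63 was at least 102-fold higher, and LjWRKY1 fell by 4.76 (SE 0.25, adjusted p = 1.34e-07). Heat shock factors rose in 14 of 21 targets, fell in 0 and did not pass in 7 (median 1.66, camera adjusted p = 0.00764), with LjHSF14 up by 8.48 (SE 0.89), but at least 2.30-fold on its other probe, and LjHSF8 up by 4.95 (SE 0.53). ERF factors rose in 46 of 99 targets and fell in 20, or 33 and 33 when scaled on probes measured on every array (median 1.48, camera adjusted p = 0.0344), and NAC and NAM factors rose in 35 of 63 and fell in 14 (median 1.42, camera adjusted p = 0.0467). LjERF5 was at least 592-fold and LjERF41 at least 269-fold higher, LjERF61_est fell by 7.11 (SE 0.50), and LjNAM24 rose by 9.20 (SE 0.60). The heat shock, ERF and NAC lists each had an adjusted p = 0.274 with an estimated correlation. The planned list of AP2/ERF, NAC and bZIP factors, met only by bZIP names, held 25 up and 12 down among 48 targets, or 16 and 19 when scaled on probes measured on every array (median 1.12, camera adjusted p = 0.114). Adjusted over the list alone it again held 25 up and 12 down. Among C2H2 zinc fingers LjZF-C2H2-34 rose from −4.43 ± 0.76 (SD, n = 4) to 8.40 ± 0.30 (n = 3), in a family with 47 of 117 targets up and 43 down (camera adjusted p = 0.808).

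Other transcription factor families were mostly lower. Of 101 bHLH targets, 59 fell, 21 rose and 21 did not pass (median −1.41, camera adjusted p = 0.00764), although LjbHLH86 was at least 758-fold higher. LjbHLH82 was at least 77.5-fold lower. Homeodomain factors fell in 32 of 59 targets and rose in 10 (median −1.32, camera adjusted p = 0.0161). Auxin response factors and repressors fell in 25 of 41 and rose in 7 (median −1.50, camera adjusted p = 0.0297), and DOF factors fell in 10 of 18 and rose in 1 (median −1.59, camera adjusted p = 0.0467). These lists had adjusted p = 0.341, 0.274, 0.341 and 0.418 with an estimated correlation. On slide 2 alone the auxin list (adjusted p = 0.0561) and the DOF list (adjusted p = 0.0955) no longer passed. The DOF median was −1.19 with members not well above background held at their bounds.

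Cytochrome P450s as a class were lower: 110 of 194 targets fell, 47 rose and 37 did not pass, the same numbers adjusted over the list alone (median −1.69, camera adjusted p = 0.00204; adjusted p = 0.341 with an estimated correlation). The families of brassinosteroid synthesis (CYP85, CYP90 and CYP724) fell in 11 of 12 targets with 0 up (median −3.42, camera adjusted p = 0.00204), and those of gibberellin synthesis and turnover (CYP88, CYP701 and CYP714) in 9 of 12 with 0 up (median −1.82, camera adjusted p = 0.0204). CYP90A_LjSGA_014057.1 was at least 43.3-fold lower and CYP88A_LjSGA_147856.1 at least 26.6-fold lower. Both lists had an adjusted p = 0.274 with an estimated correlation, and with members not well above background held at their bounds their medians were −2.71 and −1.66. The fatty acid hydroxylase families fell in 9 of 11 targets (median −1.78, camera adjusted p = 0.0236), CYP76 in 12 of 18 with 1 up (median −3.99, camera adjusted p = 0.00204), and CYP82 in 18 of 26 with 5 up (median −2.07, camera adjusted p = 0.0173). These 3 family lists had adjusted p = 0.479, 0.350 and 0.274 with an estimated correlation. CYP76E_LjT29E04.90.nd was at least 46.9-fold lower. Within CYP82, CYP82A_LjSGA_013827.2 fell by 9.26 (SE 0.62) and CYP82A_LjSGA_052400.1 rose by 7.88 (SE 0.38).

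Genes of cyanogenic glucoside metabolism, the store from which Lotus leaves release hydrogen cyanide, were mostly lower: 11 of 15 targets fell, 3 rose and 1 did not pass, the same numbers adjusted over the list alone (median −3.74, camera adjusted p = 0.0467; adjusted p = 0.642 with an estimated correlation). CYP79D3_ntc, for the enzyme that starts this pathway, was below detection on all 3 arrays and at least 150-fold lower (adjusted p = 0.00483), or at least 38.3-fold on its other probe. Its unelicited signal differed by slide, at 7.46 and 7.70 on slide 2 and at −1.86 and −2.93 on slide 1, and it also passed on slide 2 alone (adjusted p = 3.32e-08). UGT85J_LjSGA_003166.2 rose by 6.26 (SE 0.74, adjusted p = 2.66e-05), or 4.82 on slide 2 alone. Beta-glucosidases fell in 23 of 38 targets, rose in 11 and did not pass in 4 (median −2.81, camera adjusted p = 0.0467; adjusted p = 0.542 with an estimated correlation). LjBGLU4_ntc was at least 695-fold lower, LjBGLU2_ntc fell by 11.01 (SE 1.31) on 1 probe and fell by 8.33 (SE 1.20) on the other, and BGLUG2_LjSGA_034905.1 rose by 7.34 (SE 1.27). These sizes refer to the mean over both slides of the unelicited arrays, whose signals differed. A probe of LjBGLU4_ntc averaged 6.67 on slide 2 and 1.57 on slide 1. The first probe of LjBGLU2_ntc averaged 8.55 and 3.68. The rise of BGLUG2_LjSGA_034905.1 was 4.88 on slide 2 alone, its unelicited signals averaging −1.28 on slide 2 and −6.21 on slide 1. Unelicited arrays of slide 2 were above those of slide 1 by a median of 1.36 in the cyanogenic list and 0.99 in the beta-glucosidases.

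In all, 2456 of 3309 probes differed at 3 h (limma, Benjamini-Hochberg adjusted p under 0.05), 1240 higher and 1216 lower, with a median size of 2.86 among them. Scaled instead on the 75th percentile of probes well above background on every array, which moved the median of all probes from −0.05 to −1.11, 801 were higher and 1660 lower, so directions are relative to the scaling. On slide 2 alone 2581 probes passed and with the slide as a block 2638. No leaves handled in the same way without GSH are among the samples analysed here. The comparison therefore covers detachment, submersion, shaking, warmth and the time elapsed together with GSH.

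**Figure D1:**
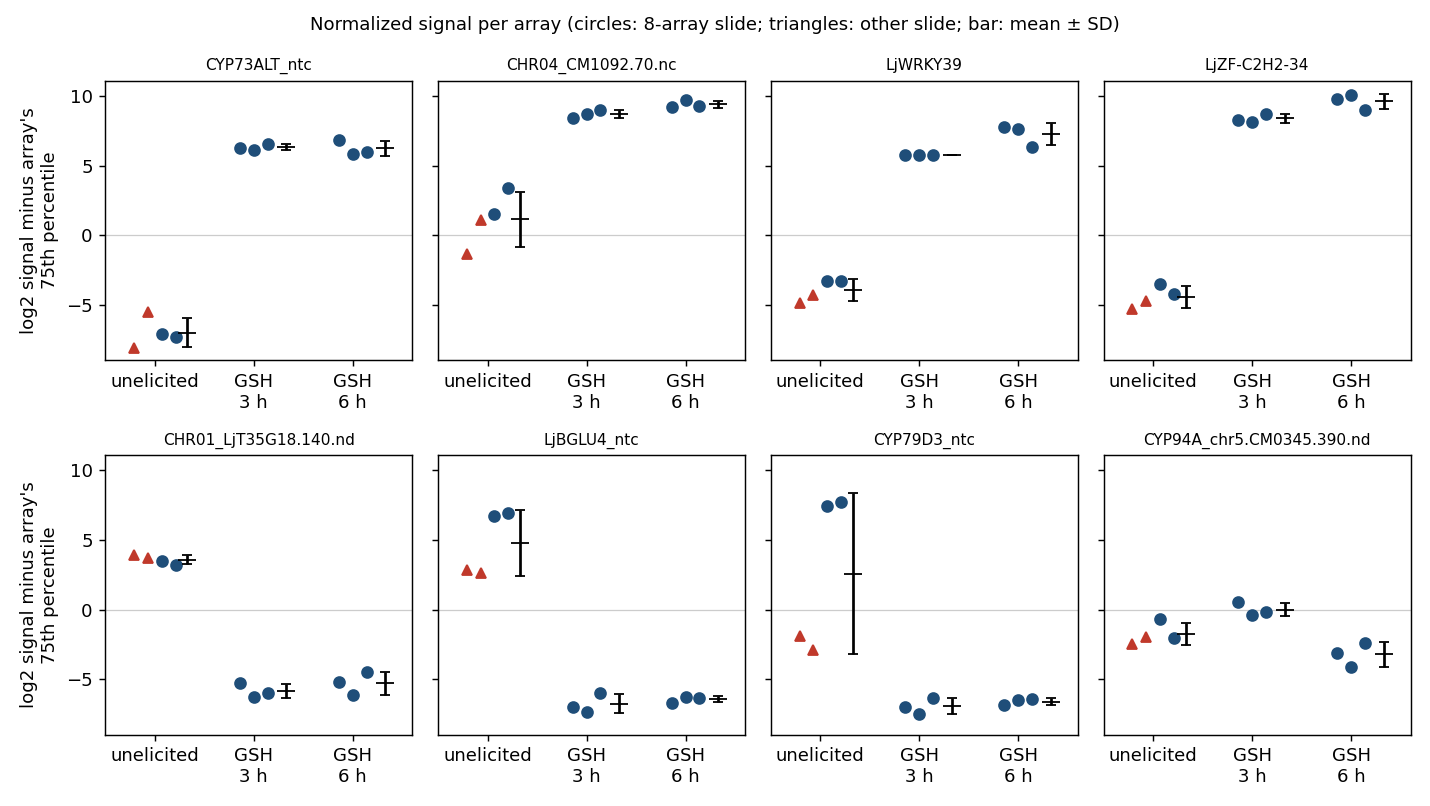
Normalized log2 signal (y axis, log2 units relative to each array's 75th percentile) of 8 probes on each of the 10 arrays, grouped on the x axis as unelicited, GSH 3 h and GSH 6 h, with circles for slide 2, triangles for slide 1 and bars for the mean ± SD. The probe shown for CYP73ALT_ntc goes from −7.00 to 6.32 and 6.24, and the unelicited arrays of CYP79D3_ntc separate by slide.

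The second comparison asks the same after 6 h. Phenylpropanoid entry and chalcone synthesis were again mostly higher, with 25 of 35 targets up and 9 down (median 3.19, camera adjusted p = 0.00355) and 25 of 41 up and 9 down (median 5.61, camera adjusted p = 0.00768). C4H02_LjSGA_003295.2 was at least 2353-fold higher on 1 probe and rose by 8.68 (SE 1.28) on the other. C4H01_chr5.LjT24B10.30.nc rose by 10.54 (SE 1.03, adjusted p = 1.21e-05), or 12.43 on slide 2 alone, and CHR04_CM1092.70.nc by 8.25 (SE 0.86, adjusted p = 1.02e-05), or 6.94 on slide 2 alone. CHS11_chr1.CM0593.380.nc fell by 7.56 (SE 0.55), and fell by 6.40 on slide 2 alone, there against 1 unelicited array. In the isoflavonoid branch 23 of 33 targets rose, 7 fell and 3 did not pass, and the list passed (median 3.64, camera adjusted p = 0.0441). CYP81ELT_1_ntc rose by 6.95 (SE 0.44), PTR1_chr3.CM0216.40.nd by 8.79 (SE 1.10) and CYP93C_chr4.CM0692.280.nc by 5.92 (SE 0.93), the latter 2 by 6.84 and 4.20 on slide 2 alone. The hydroxyisoflavanone dehydratase name HID5_chr4.CM0079.310.nc fell from 6.42 ± 1.05 (SD, n = 4) to 0.57 ± 0.41 (n = 3). With an estimated correlation these lists had adjusted p = 0.417, 0.571 and 0.631, and on slide 2 alone the isoflavonoid branch no longer passed (adjusted p = 0.0521). The planned isoflavonoid and phytoalexin list again had 6 of 7 targets up and 1 down, also when adjusted over the list alone, without passing (median 3.83, camera adjusted p = 0.0878).

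WRKY factors rose in 54 of 74 targets and fell in 11 at 6 h, or 55 and 11 adjusted over the list alone (median 3.24, camera adjusted p = 2.96e-06; adjusted p = 0.249 with an estimated correlation). LjWRKY39 reached 7.25 ± 0.78 (SD, n = 3), a rise of 11.18, and LjWRKY63 was at least 224-fold higher. Heat shock factors rose in 15 of 21 targets with 0 down (median 1.38, camera adjusted p = 0.00355), ERF factors in 47 of 99 with 25 down (median 1.19, camera adjusted p = 0.0419) and NAC and NAM factors in 36 of 63 with 13 down (median 1.30, camera adjusted p = 0.0326). Under spike-in scaling on slide 2 the NAC and NAM counts were 20 up and 21 down. With an estimated correlation each of these lists had an adjusted p = 0.249. Named rises included LjZF-C2H2-34 at 14.06 (SE 0.44, adjusted p = 8.54e-09; 9.95 with SE 3.28 on its other probe, which was dim on 1 of 3 arrays), LjERF41 at least 1080-fold, LjbHLH86 at least 1295-fold, LjHSF14 at 9.88 (SE 0.89; less on its other probe) and LjMYB12a_LjMYB31 at 10.59 (SE 0.98; 8.72 on slide 2 alone), the last of these well above background on 2 of 4 unelicited arrays. The planned bZIP list had 26 up and 12 down of 48, also when adjusted over the list alone (median 1.17, camera adjusted p = 0.0644), and it passed on slide 2 alone (adjusted p = 0.0316).

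Among factors mostly lower at 6 h, bHLH fell in 59 of 101 targets with 15 up (median −1.47, camera adjusted p = 0.00355) and homeodomain factors in 35 of 59 with 6 up (median −1.67, camera adjusted p = 0.0186). The auxin list fell in 27 of 41 with 7 up (median −1.85, camera adjusted p = 0.0223), DOF in 14 of 18 with 1 up (median −1.02, camera adjusted p = 0.0419) and B3 factors in 23 of 43 with 7 up (median −1.36, camera adjusted p = 0.0189). With an estimated correlation their adjusted p = 0.266, 0.266, 0.336, 0.417 and 0.249, and DOF no longer passed on slide 2 alone (adjusted p = 0.0911). The auxin list passed there with the probes used throughout (adjusted p = 0.0399) but not with the probes brightest on slide 2 (adjusted p = 0.0581). With members not well above background held at their bounds, the medians of the homeodomain and B3 lists were −1.26 and −1.04. LjERF61_est was at least 148-fold lower.

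Cytochrome P450s fell in 108 of 194 targets and rose in 48 at 6 h, or 109 and 48 adjusted over the list alone (median −1.87, camera adjusted p = 0.00355; adjusted p = 0.383 with an estimated correlation). All 12 brassinosteroid family targets fell (median −2.66, camera adjusted p = 0.00355), as did 7 of 12 gibberellin family targets with 0 up (median −1.51, camera adjusted p = 0.0442). Both lists had an adjusted p = 0.249 with an estimated correlation. CYP88A_LjSGA_147856.1 was at least 20.9-fold lower. CYP76 fell in 13 of 18 targets with 3 up (median −3.49, camera adjusted p = 0.0104), CYP82 in 18 of 26 with 7 up (median −2.88, camera adjusted p = 0.0262) and the fatty acid hydroxylase families in 9 of 11 with 0 up (median −2.50, camera adjusted p = 0.0223). With an estimated correlation their adjusted p = 0.417, 0.249 and 0.518. CYP82A_LjSGA_013827.2 was at least 576-fold lower. In cyanogenic glucoside metabolism 12 of 15 targets fell and 3 rose, the same numbers adjusted over the list alone (median −3.76, camera adjusted p = 0.0419), and 24 of 38 beta-glucosidases fell with 10 up (median −2.99, camera adjusted p = 0.0419). These lists had adjusted p = 0.631 and 0.571 with an estimated correlation. With members not well above background held at their bounds the medians were −1.38 in the P450s, −1.09 in the gibberellin list, −1.95 in the fatty acid hydroxylase families and −2.46 in the beta-glucosidases. CYP79D3_ntc was at least 118-fold lower, or 30.1-fold on its other probe, and LjBGLU4_ntc at least 546-fold lower. LjBGLU2_ntc was at least 1360-fold lower on 1 probe and fell by 8.49 (SE 1.20) on the other. As at 3 h, these sizes refer to the mean over both slides, between which unelicited signals of both beta-glucosidases differed. UGT85J_LjSGA_003166.2 rose by 6.33 (SE 0.74), or 4.89 on slide 2 alone.

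At 6 h, 2511 of 3309 probes differed (limma, Benjamini-Hochberg adjusted p under 0.05), 1240 higher and 1271 lower, with a median size of 2.96. With the scaling on probes measured on every array the split was 835 higher and 1680 lower. On slide 2 alone 2617 probes passed, and 2671 with the slide as a block. As at 3 h, handling without GSH and the time elapsed were not separated from GSH in the samples analysed here.

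**Figure D2:**
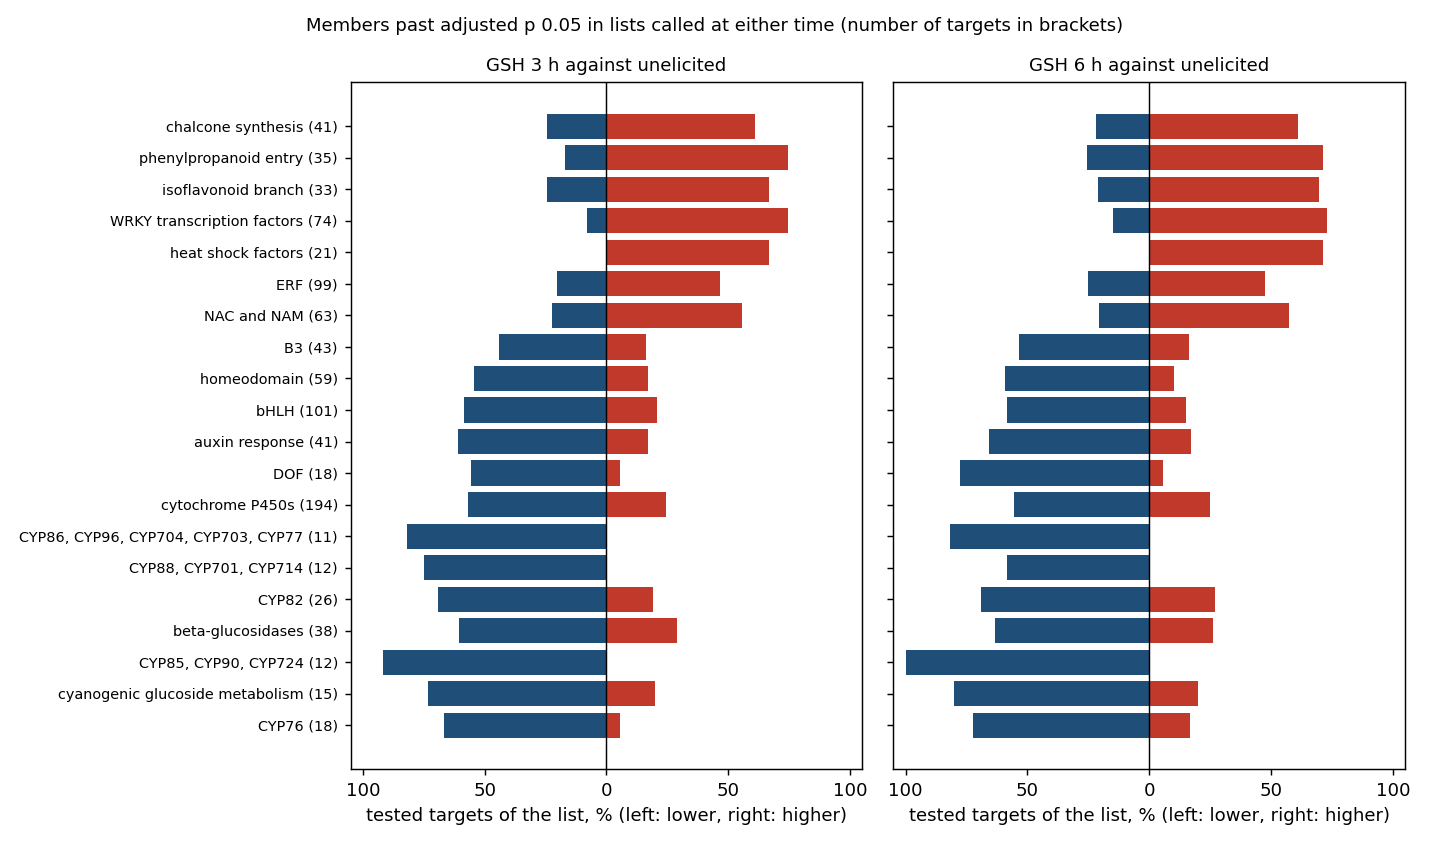
Share of each list's tested targets (x axis, %) that passed the test, higher to the right and lower to the left of 0, at 3 h and at 6 h, for lists called at either time with the number of targets in brackets. WRKY factors reach 55 of 74 targets higher at 3 h, and the CYP85, CYP90 and CYP724 families 12 of 12 lower at 6 h.

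The third comparison asks whether leaves differed between 3 h and 6 h. Genes that were still rising included transcription factors: LjMYB21 went from below detection in unelicited leaves to −0.40 ± 0.41 at 3 h and 2.23 ± 0.90 at 6 h (SD, n = 3), a difference of 2.63 (SE 0.49, adjusted p = 0.0167). LjHD19 was 2.41 higher at 6 h (SE 0.53, adjusted p = 0.0290), LjWRKY25 2.07 (SE 0.35, adjusted p = 0.0110) and LjHSF16 1.49 (SE 0.30, adjusted p = 0.0208). With the slide as a block adjusted p = 0.00555 for LjMYB21, 0.00604 for LjHD19, 0.00184 for LjWRKY25 and 0.00385 for LjHSF16. All of them also passed on slide 2 alone, a fit that holds the same GSH arrays. These calls depend on the arrays and settings used: LjHD19 lost its call without any 1 of the 6 GSH arrays (adjusted p 0.0504 to 0.133) and LjHSF16 without any of them but GSH 6 h replicate 3 (0.0642 to 0.0949), and both lost it with quantile normalization (0.0662 and 0.0587) and the replicate number as a block (0.0645 and 0.0647). LjMYB21 and LjWRKY25 lost theirs without GSH 3 h replicate 1 (0.0835 and 0.0553), GSH 3 h replicate 3 (0.0506 and 0.0512) or GSH 6 h replicate 2 (0.0764 and 0.0557), and LjMYB21 also with the replicate block (0.0515). With normexp LjMYB21 (0.0798), LjWRKY25 (0.0723) and LjHSF16 (0.0997) did not pass, nor did the other probes of LjWRKY25 (1.58, adjusted p = 0.115) and LjHSF16 (1.28, adjusted p = 0.356). LjNAM45 was higher by 3.85 (SE 0.43, adjusted p = 0.00252) and LjERF4 by 3.37 (SE 0.35, adjusted p = 0.00251), but with normexp background correction they differed by 2.68 (adjusted p = 0.0637) and 0.80 (adjusted p = 0.707). Probes below detection at 3 h and measured on all 3 arrays at 6 h were UGT74K_chr2.CM1150.40.nd, at least 9.12-fold higher (3.54 on its other probe, which was measured at 3 h, adjusted p = 0.0266), LjWRKY42, at least 7.72-fold, FSulph01_chr4.CM0087.400.nc, at least 6.44-fold (2.78-fold on its other probe), and LjNAM72, at least 5.62-fold. With normexp these 4 differed by 0.81, 0.72, 0.55 and 0.49 and did not pass. F3H01_chr3.CM0208.350.nc was 4.53 higher (SE 1.11, adjusted p = 0.0447), with 3 h signals of −6.61, −1.57 and −6.28, and it kept its call only when unelicited replicate 1 or GSH 3 h replicate 2 was the array left out (adjusted p 0.0545 to 0.171 otherwise). It also lost it with normexp (1.92, adjusted p = 0.276), quantile normalization (0.0689), no filter (0.0648), the arrays of the 2 groups alone (0.0611), the replicate block (0.0515) and 1 probe per target (0.0511).

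Other genes were lower at 6 h than at 3 h. The P450 probes CYP94A_chr5.CM0345.390.nd and CYP94A_LjT22H02.40.nc, above their unelicited signals of −1.77 and −0.96 at 3 h with −0.01 and 1.25, dropped by 3.20 (SE 0.55, adjusted p = 0.0112) and 2.98 (SE 0.65, adjusted p = 0.0288). CYP94A_LjT22H02.40.nc lost its call with quantile normalization (adjusted p = 0.123), normexp (0.0997) and the replicate number as a block (0.0503), and without any GSH array but GSH 6 h replicate 3 (0.0673 to 0.131). CYP94A_chr5.CM0345.390.nd lost it without GSH 3 h replicate 1 (0.0687) or GSH 6 h replicate 2 (0.0557), and its other probe differed by −0.55 and did not pass (adjusted p = 0.606). AAT01_LjSGA_011608.1, measured on the 3 arrays at 3 h alone, was at least 2.78-fold lower at 6 h, and BGLU63_LjSGA_077946.1 at least 4.46-fold lower. Both lost their calls with normexp (0.369 and 0.275), AAT01_LjSGA_011608.1 also without GSH 3 h replicate 1 (0.0525) or GSH 6 h replicate 2 (0.0557), and BGLU63_LjSGA_077946.1 with quantile normalization (0.0689) and without any GSH array but GSH 6 h replicate 3 (0.0523 to 0.0904). LjbHLH3 passed only narrowly, by −2.60 (SE 0.65, adjusted p = 0.0475), and its other probe differed by −0.33 and did not pass (adjusted p = 0.871). It lost its call without any array other than GSH 6 h replicate 3 (0.0522 to 0.177) and with normexp (0.199), quantile normalization (0.0747), the other 75th percentile (0.0594), no filter (0.0745), the arrays of the 2 groups alone (0.0566), the replicate block (0.0506) and 1 probe per target (0.0533). Of 12 brassinosteroid family members, 2 that had fallen at 3 h were higher at 6 h than at 3 h: CYP90C_chr2.CM0249.430.nc by 1.45 (SE 0.30, adjusted p = 0.0253) and CYP90A_LjSGA_014057.1, not well above background at 3 h, at least 1.99-fold (adjusted p = 0.00917). The difference of CYP90A_LjSGA_014057.1 was −0.26 with normexp, and it lost its call without GSH 3 h replicate 1 (0.0525) or GSH 6 h replicate 2 (0.0516). CYP90C_chr2.CM0249.430.nc lost its call without GSH 3 h replicate 1 (0.105) or 3 (0.0804) or GSH 6 h replicate 2 (0.115) or 3 (0.0557), and with normexp (0.324), quantile normalization (0.0821), no filter (0.0526), the replicate block (0.0551) and spike-in scaling on slide 2 (0.156). The cinnamate 4-hydroxylase probe CYP73A_LjSGA_031602.1 and the chalcone synthase probe CHS17_chr2.CM0018.680.nc, at high signals of 8.92 and 9.25 at 3 h, differed by 0.03 (SE 0.28, adjusted p = 0.970) and 0.19 (SE 0.69, adjusted p = 0.923), with either sign depending on the scaling.

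As groups, WRKY factors were higher at 6 h by a median of 0.45, with 5 of 74 targets past the threshold upwards and 1 downwards, or 6 and 2 adjusted over the list alone, but their median was −0.12 under spike-in scaling on slide 2. Phenylpropanoid entry was lower by a median of −0.55 with 0 of 35 targets passing, and B3 factors by a median of −0.38, or −0.24 with dim members at their bounds, with 1 of 43 lower. Each had camera adjusted p = 0.00492. With an estimated correlation WRKY factors and phenylpropanoid entry had an adjusted p = 0.856 and B3 factors 0.136. The other planned lists did not pass between the times, with medians of 0.10 in the P450s (camera adjusted p = 0.642), −0.03 in cyanogenic glucoside metabolism (0.700), −0.32 in the isoflavonoid and phytoalexin list (0.875) and 0.16 in the bZIP list (0.642).

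In all, 177 of 3309 probes differed between the times, 111 higher and 66 lower at 6 h. Of the 111, 59 had risen at both times and 30 had fallen at 3 h, and of the 66, 30 had risen at 3 h and 15 had fallen at both times. This number is fragile: it was 26 without GSH 6 h replicate 2, 29 without GSH 3 h replicate 1, 54 without GSH 3 h replicate 3, 88 without GSH 3 h replicate 2 and 106 without GSH 6 h replicate 1. The spread behind this number includes the slide difference among unelicited arrays, although all GSH arrays are on slide 2. The number was 505 on slide 2 alone and 657 with the slide as a block. Both included all 177, and so every probe named above that had passed. Both fits use the same GSH arrays and differ from the main fit in the estimate of the spread, so this is no independent check. Spike-in scaling within slide 2 gave 96 higher and 712 lower.

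The responses at the 2 times were compared directly. Across the 3309 probes, which are not independent replicates, the log2 fold changes at 3 h and 6 h had a Pearson r of 0.966. In 100 simulated draws of unchanged groups sharing the same unelicited arrays, r averaged 0.427 with a highest value of 0.486. The covariance averaged 0.122, which lies 11.9 below the covariance observed. The draws held no slide difference, which both comparisons share through the unelicited arrays. Their r, covariance and shared calls are therefore not the no-change values of these arrays. With the unelicited arrays split between the comparisons, r lay between 0.863 and 0.959 with a lowest covariance of 11.4, the lowest r and covariance when the split followed the slides. A total of 1123 probes rose at both times and 1106 fell at both, against 465 and 467 for independent lists of the same sizes and at most 1 shared call in any simulated draw with the unelicited arrays shared. A single probe rose and then fell, and 3 fell and then rose. LjWRKY39, LjbHLH86 and CYP73ALT_ntc are among the genes up at both times, and LjBGLU4_ntc, CHR01_LjT35G18.140.nd and CYP94D_chr1.LjT01M20.50.nc among those down at both.

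**Figure D3:**
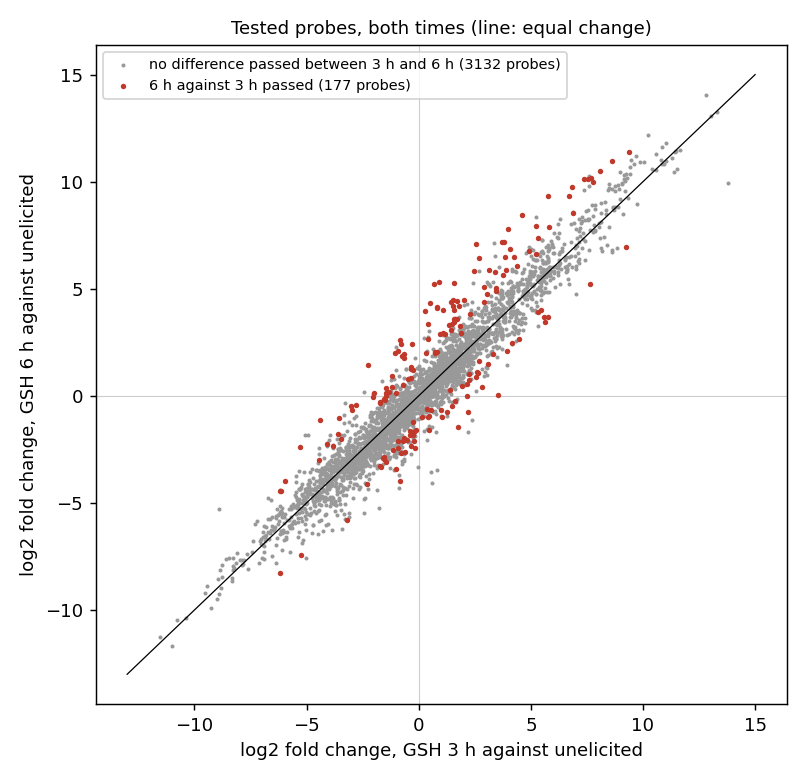
Log2 fold change against unelicited leaves at 3 h (x axis) and at 6 h (y axis) for the tested probes, with the 177 probes that differed between 6 h and 3 h in red and the line of equal change. The points follow the line, with r = 0.966 across probes.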

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

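All of these tests except the splits of the samples were added after the data had been examined. For the spike-in scaling, the probe pairs and the likeness to the GSH response, the outcomes that would count for or against an explanation were written before the test was run. For the slide, the number of probes under other scalings, the handling, a smooth labelling effect and an exchange of arrays they were written with the results already seen.

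The first pattern is that most tested probes changed after GSH. Of the 35 splits of the unelicited and 3 h arrays into 4 and 3, only the real 1 gave as many probes (2456, highest other 1281). Of the 35 splits at 6 h it was again only the real 1 (2511, highest other 1306). A share of 1 in 35 argues against chance but cannot exclude it. The splits also exchange arrays between slides, although all GSH arrays are on slide 2. The slide as the whole cause is argued against, since 92.9% of the 3 h calls passed with their direction on slide 2 alone. Scaling on the 75th percentile as the cause of the number is argued against, since at least 69.7% of tested probes passed under each of the other 4 scalings. The line for this, 50%, was written with the results already seen. Normexp background correction, which keeps the 75th percentile scaling and was not among the 4, left 1576 of 3309 at 3 h, under 50%. The number therefore differs with this setting. It also took median spot signals in place of the processed signal and an offset of 50, and which part lowered the number was not tested. For the directions scaling stays open, since 86.3% of the slide 2 calls at 3 h kept theirs under spike-in scaling. This lies between the 50% and 90% written before that test was run. Handling of detached leaves without GSH, with the time elapsed, cannot be told apart from GSH, with 0 arrays of such leaves. A response to GSH itself stays a hypothesis beside it.

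The second pattern is that unelicited replicates 1 and 2 differ from 3 and 4, by over 2-fold in 702 probes upwards and 786 downwards on slide 2 and by over 16-fold in 44 and 22. A labelling or scan effect smooth in signal is argued against as the whole cause, since the SD of the difference after a loess fit stayed 2.43 times the largest SD within a slide (0.62), but a technical part is not excluded: 8 spike-ins, which carry no leaf RNA, shifted by 1.69 to 4.14 against 1.56 for the 75th percentile, and the highest signals were 12100 and 19700 on slide 1 against 248000 or more on slide 2. Probe-by-probe hybridisation differences are argued against by a correlation of 0.754 between the 2 probes of 1302 names, and an exchange with GSH arrays by a lowest correlation of 0.827 among unelicited arrays against at most 0.452 with GSH arrays. A partial form of the GSH response across all probes is argued against by a correlation of 0.0184 with the 3 h change. It cannot decide this for part of the genes, since the largest differences went both ways. Slide 1 lay towards the GSH signal for CYP79D3_ntc (9.98 on slide 2 over slide 1, −9.52 at 3 h) and CYP73ALT_ntc (−5.39, 8.76). It lay away from it for IFR7_chr2.CM0249.1080.nc (5.42, 4.99) and BGLUG2_LjSGA_034905.1 (4.93, 7.34). The labels name no difference between these samples, so no other biological explanation was tested and it stays open whether leaves, harvest or RNA handling differed.

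The differences between 6 h and 3 h stood out because the 2 times differ from each other in a direct test. The count of 177 probes came with a highest other of 0, but 10 splits are too few for a share under 0.05 (1 of 10 at best). Higher at 6 h were F3H01_chr3.CM0208.350.nc (4.53), LjNAM45 (3.85), LjERF4 (3.37), LjMYB21 (2.63), LjHD19 (2.41), LjWRKY25 (2.07), LjHSF16 (1.49) and CYP90C_chr2.CM0249.430.nc (1.45), as log2 differences of group means. Lower at 6 h were CYP94A_chr5.CM0345.390.nd (−3.20), CYP94A_LjT22H02.40.nc (−2.98) and LjbHLH3 (−2.60). Where 1 of the times was not well above background on any array, the fitted difference is no measured size and only the bound holds: FSulph01_chr4.CM0087.400.nc (4.54, at least 6.44-fold higher), UGT74K_chr2.CM1150.40.nd (4.42, at least 9.12-fold), LjNAM72 (3.84, at least 5.62-fold), LjWRKY42 (3.67, at least 7.72-fold), CYP90A_LjSGA_014057.1 (1.74, at least 1.99-fold), AAT01_LjSGA_011608.1 (−3.48, at least 2.78-fold lower) and BGLU63_LjSGA_077946.1 (−3.16, at least 4.46-fold lower). The list medians were 0.45 in WRKY factors, −0.55 in phenylpropanoid entry and −0.38 in B3 factors. Of 60 named probes checked for 1 unelicited array far from the other 3, 0 had one, where chance would give 1 in 20. The check can hardly find one where the unelicited arrays split by slide, so it does not show that they agree.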

How the results depend on the processing

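Normexp on the median signals, slide 2 alone and spike-in scaling within slide 2 were chosen after seeing the data. The counts at 3 h and 6 h stayed within 1.5 times the reported ones except for normexp at 3 h (1576), only probes well above background on all arrays (1499 and 1523 of 2114 tested) and 1 probe per target (1453 and 1472 of 1970), the latter pairs testing fewer probes; the cause of the normexp change was not tested. Normexp moved the median of all probes at 3 h from −0.05 to 0.30 and the share of changed probes that were higher from 50.5% to 63.3%. The other scalings moved the median to −0.18 (quantile), 0.15 (median), −1.11 (75th percentile of probes measured on all arrays) and −0.55 (spike-ins, slide 2). With them the share became 48.2%, 53.8%, 32.5% and 40.5%. Leaving out each array gave 2237 to 2459 at 3 h and 2311 to 2528 at 6 h. The 177 probes between the times became 19 with normexp, 112 with quantile normalization, 109 with no filter and 84 with 1 probe per target. They became 823 with array weights and 1 with a plain test per probe. Each array left out gave 26 (without GSH 6 h replicate 2) to 194. The cause of these changes was not tested. The spread shared by the main fit includes the slide difference among unelicited arrays, although all GSH arrays are on slide 2. Limma fits without that difference gave more. They called 404 with only the arrays of the 2 groups, 505 on slide 2 and 657 with the slide or the scan as a block. With spike-ins on slide 2 the number was 808 (11.9% higher against 62.7%). The correlation of the responses was 0.968 with quantile normalization, 0.960 with no filter, 0.963 with probes measured on all arrays and 0.963 with array weights, and 0.961 to 0.967 with each array left out. Lists called at 3 h, at 6 h and between the times were 18, 20 and 3; an estimated correlation per list gave 0, 0 and 0, fry 42, 42 and 5, and probes measured on all arrays 10 at 6 h, while leaving out arrays gave 14 to 18, 15 to 20 and 3 to 4. Of 41 named values at each of 3 h and 6 h, 39 and 41 kept direction and call in every alternative that tested them. The other 2, I2H1_chr2.CM0250.70.nc and CYP79D_LjSGA_030566.2 at 3 h, lost the call with normexp. Of 20 between the times, 0 kept both in every such alternative. The plain test was not applied to named values, and some settings did not test every named probe. Most were named for their large changes in the main fit, so keeping the call at 3 h and 6 h was likely beforehand. Reversed were CYP90A_LjSGA_014057.1 with normexp (−0.26), CHS17_chr2.CM0018.680.nc with spike-ins (−0.42) and CYP73A_LjSGA_031602.1 with quantile normalization (−0.31), with spike-ins (−0.58), without GSH 3 h replicate 1 (−0.12) and without GSH 6 h replicate 2 (−0.12), its highest value being 0.18 without GSH 3 h replicate 3 among arrays left out; the last 2 genes had not passed, and the cause was not tested.

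Replicate numbers showed no sign of pairing the samples: same-numbered arrays of different groups correlated at −0.04 to 0.06 in their deviations, and 0 of 9 pairs exceeded 0.1. Deviations of unelicited arrays carry the slide difference, which can hide a pairing. The same-numbered pairs of 3 h and 6 h arrays, all on slide 2, correlated at −0.042, 0.055 and −0.018. With the number as a block 2432, 2461 and 80 probes passed, the last below the reported 177, lists came to 17, 21 and 3 and r to 0.965. No list value exists for a fold threshold, a plain test or 1 probe per target (already in use), and normexp on mean spot signals could not be run because these files lack that column. Signal over background limits the falls most: 29.1% of probes lower at 3 h and 34.1% at 6 h were not well above background on any GSH array, so their size is a bound, against 8.95% and 9.35% of the probes that rose.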

Other observations

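Other gene families on the array moved in both directions without passing as groups. UDP-glycosyltransferases, which attach sugars to small molecules, had 60 targets up, 63 down and 24 not passing of 147 at 3 h (median −0.14 and mean 0.14, opposite in sign; camera adjusted p = 0.932), and 61 up and 62 down at 6 h. MYB factors had 35 up and 26 down of 75 at 3 h (median 1.00, camera adjusted p = 0.327) and 38 up and 22 down at 6 h (median 1.35, camera adjusted p = 0.166), with LjMYB12a_LjMYB31 up by 11.54 (SE 0.98) at 3 h, or 9.66 on slide 2 alone. RING-type zinc fingers had 87 up and 67 down of 230 at 3 h (camera adjusted p = 0.515), and GRAS factors 14 up and 13 down of 39 (camera adjusted p = 0.942).

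The CYP74 and CYP94 families, which hold enzymes of oxylipin and jasmonate metabolism, had 9 up, 4 down and 3 not passing of 16 at 3 h (median 1.80, or 1.34 with dim members at their bounds, camera adjusted p = 0.328). CYP94C_LjT01G11.220.nd was below detection in unelicited leaves and at least 121-fold higher at 6 h (29.6-fold on its other probe), CYP94A_chr1.CM0375.290.nd rose by 8.03 (SE 0.36) at 6 h, and CYP94D_chr1.LjT01M20.50.nc was at least 177-fold lower at 3 h. Flavonol, anthocyanidin and tannin names, beside the isoflavonoid branch, had 8 up and 13 down of 27 at 3 h (median −1.05, camera adjusted p = 0.418). Laccases had 1 up and 4 down of 6 (median −4.30, or −2.15 with dim members at their bounds, camera adjusted p = 0.114) and dirigent proteins 7 up and 2 down of 10 (camera adjusted p = 0.0984). Names of flower and meristem regulators (MADS, LEAFY and YABBY), taken as markers of other organs, had 6 up and 12 down of 24 at 3 h (median −1.26, camera adjusted p = 0.311).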
